A study of Acipenser schrenckii with 6 samples.

How the data were processed

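Poly(A) RNA was sequenced from gut tissue of Amur sturgeon (Acipenser schrenckii), in 3 libraries from fish given commercial feed and 3 from fish given fresh Limnodrilus worms for 30 days. Per the labels' protocols, total RNA was extracted with a commercial kit, RNA with an integrity number above 7.0 was taken on, poly(A) RNA was captured on oligo(dT) beads and fragmented, and the second strand was digested before amplification. The labels do not say whether a library came from 1 fish or from pooled fish, so p-values measure the spread between these samples, which may in part be technical.

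The values are FPKM (fragments per kilobase of length, scaled to the library total) that the authors deposited in 1 table of 82023 features with a length for each. Per the submitters' processing notes, cutadapt 1.9 was used and the build named is mm10, a mouse build. The table itself uses RefSeq sequence names with LOC and Q747 gene identifiers on 1032 sequences, which are not names of that build. The assembly, the aligner, the counting tool, the use of strand and the treatment of reads that match several places are not given in the sources used here, and coordinates are printed as the deposited table gives them. Of the features, 64272 carry a locus number in place of a symbol, 8765 have no product name and 2126 are named as additions beside the annotation. No column of per-sample values was left unused.

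Library depth was recovered from the deposited FPKM. In each library, FPKM times length was a whole multiple of 1 step, within 0.1 of a whole number, for 100% of the values up to about 20 reads and for 93.1% to 95.9% of all values. The step gave totals of 10.3, 9.95 and 10.5 M reads or fragments for commercial feed libraries 1 to 3, and 13.9, 19.7 and 17.0 M for Limnodrilus libraries 1 to 3. At a length of 1 kb, 3 reads correspond to 0.286 to 0.302 FPKM in the commercial feed libraries and 0.153 to 0.216 in the Limnodrilus libraries. Floors and bounds made from 3 reads cover counting error only, since PCR copies are not independent molecules.

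Computed here were log2(FPKM + 1) values for the 23644 features with a mean of at least 1 FPKM over the 6 libraries. Diets were compared with limma 3.58.1 in R 4.3.3, using the empirical Bayes trend (limma-trend), 2-sided, with Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05. Log2 fold changes are Limnodrilus minus commercial feed on the log2(FPKM + 1) scale, which understates the change of low features. The planned count-based test was not applicable because the table holds FPKM. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1.

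Before the data were examined, 29 gene lists with 572 symbols were fixed, and 473 symbols matched 1377 features, 1265 of them through the protein name. A match of acadsb to the listed acads, another gene, was left out (1 feature). The 28 lists with at least 4 tested features were compared with limma's camera at a preset correlation between genes of 0.01, with an adjustment over the 28 lists. Many listed proteins have several loci in this annotation, and reads shared between near-identical copies could be split between them, so values of single loci are uncertain to that extent. The genes named were set by a rule: in each direction the 12 called features of largest log2 fold change whose 3 libraries of one diet lie above the 3 of the other and whose annotation names a protein, from each list up to 4 called features of smallest p and the most abundant member, and the 5 most abundant features of each diet. This gave 114 features, 85 of them called. A further 16 lists defined on product names or gene identifiers were added after the fold changes had been seen.

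The test was tried on simulated data with the per-feature spread and depth of the 6 libraries and 50 of 23644 features changed at each fold. For the simulated comparison of Limnodrilus with commercial feed, 0% of features changed 2-fold, 16% of those changed 4-fold, 56% of those changed 8-fold and 80% of those changed 16-fold were called, with 4 calls among unchanged features and 0 calls when no feature was changed. Power in the data themselves depends on how many features change.

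Other settings tried were a pseudocount of 0.1, no filter or a minimum mean of 5 FPKM, TPM, median-of-ratios and quantile scaling, limma without trend, robust limma-trend, the replicate number as a block, leaving out each library, other thresholds, camera with an estimated correlation, fry and 1 feature per symbol. Chosen after seeing the data were limma-voom on the recovered reads, reads thinned to 9.948 M in every library, FPKM computed without rRNA, tRNA and mitochondrial features, removal of each library's trend with gene length (with and without its overall level kept) and leaving out commercial feed libraries 1 and 2 together.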

Results

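Gut gene expression was measured in Amur sturgeon held in net cages before release to a river, to ask whether feeding the live tubificid worm Limnodrilus in place of commercial feed for 30 days changes it. There were 3 libraries per diet, with recovered totals of 9.95 to 10.5 M reads for commercial feed and 13.9 to 19.7 M for Limnodrilus. Values above 0 were found for 31269 to 33771 features in the commercial feed libraries and for 36554 to 37401 in the Limnodrilus libraries, so depth and diet differ together.

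The 2 diets separated along the first principal component, which held 51.7% of the variance of the 23644 tested features, and the commercial feed libraries lay far apart from each other on the second, which held 24.8%. Spearman correlations were 0.866 to 0.921 among the Limnodrilus libraries, 0.625 to 0.765 among the commercial feed libraries and 0.510 to 0.653 between diets. Smooth muscle markers averaged 7.00, 6.35 and 4.13 on the log2(FPKM + 1) scale in commercial feed libraries 1, 2 and 3, and 6.14, 5.58 and 5.73 in the Limnodrilus libraries. Brush-border genes averaged 1.49, 2.91 and 4.33 in the commercial feed libraries against 4.70, 5.27 and 4.13, and interferon response genes 1.61, 1.995 and 4.10 against 2.75, 2.48 and 2.76. Commercial feed libraries 1 and 2 were thus high in muscle markers and low in brush-border and interferon genes, and library 3 the reverse. Junction genes were at 2.165, 2.088 and 2.592 in the commercial feed libraries and at 3.497 to 3.861 with Limnodrilus, so library 3 lay near libraries 1 and 2 there. Mitochondrial features took 23.7% of the recovered reads in commercial feed library 1 and 2.06% to 6.42% in the other 5 libraries. Ribosomal RNA features took 0.927% to 2.87% in the commercial feed libraries and 0.151% to 0.354% in the Limnodrilus libraries.

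**Figure D1:**
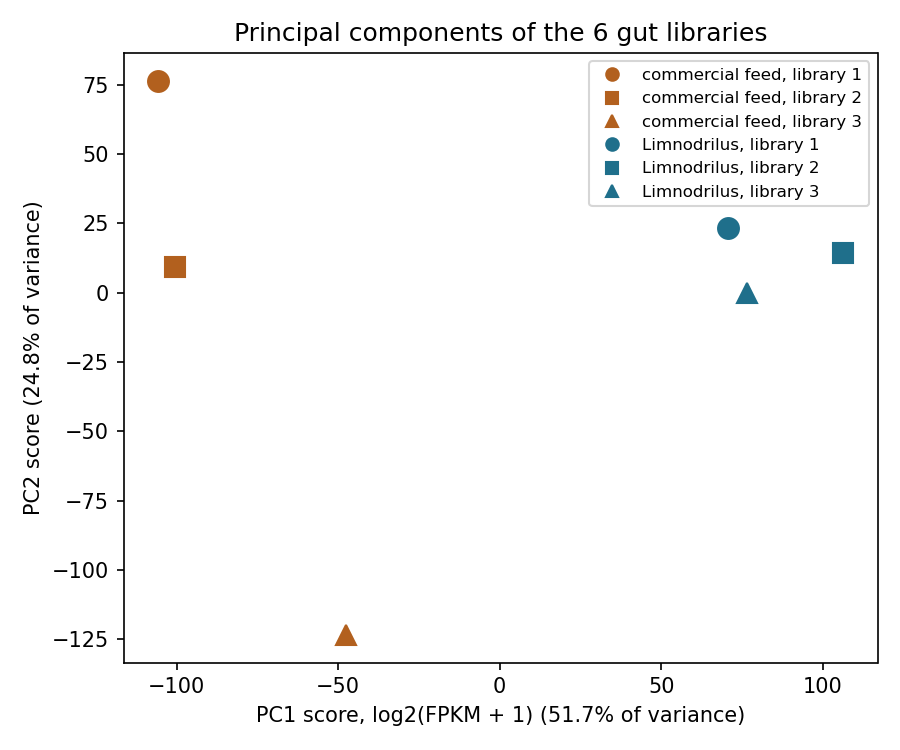
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance on each axis. Each point is a library, coloured by diet. Commercial feed library 3 lies at -123.38 on the second component and library 1 at 76.47.

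Between diets 4182 of the 23644 features passed the limma-trend test at an adjusted p under 0.05, of which 3321 were higher and 861 lower with Limnodrilus. The groups did not overlap for 39.9% of the tested features, where the average over all splits into 3 against 3 is 10%. Features vary together, so a split can exceed that average whatever its cause. The median log2 fold change of all tested features was 0.243, and under median-of-ratios scaling, which brought it to 0.009, 2235 features were higher and 1492 lower (59.97% higher, against 79.4% on the deposited scale). Under quantile normalization the numbers were 2298 and 1643 (58.3% higher), with a median of -0.03. The counts higher and lower were 563 and 75, 641 and 66, or 659 and 80 when Limnodrilus library 3, 2 or 1 was left out (638, 707 and 739 in all), 1479 and 383 without commercial feed library 2 (1862 in all), and 4883 and 1412 without commercial feed library 3 (6295 in all). Without commercial feed libraries 1 and 2 together, which leaves 1 library of that diet, 3901 features passed, 1981 higher and 1920 lower.

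The features that rose most with Limnodrilus included carriers of lipids and bile acids, an acute-phase protein and metabolic enzymes. The gastrotropin-like locus LOC117431101 (NC_081211.1, 23494583 to 23496318), an ileal bile acid-binding protein, averaged 85.7 ± 21.6 FPKM (SD over the 3 libraries of a diet here and below) with commercial feed and 3515 ± 2389 with Limnodrilus, a log2 fold change of 5.15 ± 0.544 (SE; limma adjusted p = 0.00758). The inositol-3-phosphate synthase 1-A-like locus LOC131721867 (NC_081237.1, 8442738 to 8450937), the enzyme that makes inositol phosphate from glucose 6-phosphate, went from 0.599 ± 0.288 to 46.7 ± 8.51 FPKM. Serum amyloid P-component-like LOC117973264 (NC_081209.1, 5572528 to 5573183), a pentraxin, was at 0 in the 3 commercial feed libraries and at 27.2 ± 5.12 FPKM with Limnodrilus, which is at least 61.0-fold above the mean floor of 3 reads per commercial feed library. Type-4 ice-structuring protein LS-12-like LOC117395486 averaged 30.8 ± 47.5 and 1119 ± 1551 FPKM, apolipoprotein C-I-like LOC131730504 46.9 ± 73.9 and 764.5 ± 560, apolipoprotein A-I-like LOC117964915 38.99 ± 46.5 and 848.7 ± 772, and retinol-binding protein 2-like LOC117416438 11.6 ± 18.7 and 278.5 ± 284, with log2 fold changes of 5.45, 5.39, 4.89 and 5.33. Cytosolic phosphoenolpyruvate carboxykinase LOC131698561, a gluconeogenic enzyme, averaged 0.0741 ± 0.0732 and 43.5 ± 49.5 FPKM. The ZFP36-like mRNA decay activator LOC117395242 averaged 1.16 ± 0.894 and 70.4 ± 49.2, the class I histocompatibility antigen LOC131709128 3.09 ± 2.7 and 104.8 ± 62.2, and the fibrinogen-like protein 1-like loci LOC117418487 and LOC131697566 0.879 ± 1.17 and 69.0 ± 53.4, and 4.60 ± 5.41 and 117.2 ± 48.5. Of the 85 called features that the naming rule gave, 39 have a diet mean of at least 1 FPKM that moves by over 1.5 times without 1 of its own 3 libraries, and such means are given at the end of the paragraphs that name them. LOC117395486 averaged 3.4, LOC131730504 4.187, LOC117416438 0.7868, LOC117395242 0.743, LOC117964915 12.68, LOC131709128 1.772 and LOC131697566 1.493 FPKM without commercial feed library 3. LOC117395486 averaged 223.9, LOC131730504 451.7, LOC117416438 117.7, LOC117418487 38.29, LOC117395242 42.26, LOC117964915 415.3, LOC131709128 69.05 and LOC131698561 14.97 FPKM without Limnodrilus library 2. LOC117431101 averaged 2176 FPKM without Limnodrilus library 1.

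The 12 named falls were led by 2 loci for S100-G-like calcium-binding proteins, by neil1, a DNA glycosylase of base excision repair, and by a dipeptidase 2-like locus (log2 fold change -3.51). LOC117395457 and LOC117968291, both S100-G-like, averaged 83.4 ± 66.5 and 35.9 ± 34.6 FPKM with commercial feed and 1.901 ± 0.941 and 0.910 ± 0.762 with Limnodrilus, log2 fold changes of -4.60 and -3.88. neil1 went from 173 ± 31.9 to 8.49 ± 6.47 FPKM (log2 fold change -4.52 ± 0.642 SE, limma adjusted p = 0.00903). The splicing factor SRSF5-like locus LOC117419758 went from 555.8 ± 112 to 55.2 ± 16.6 FPKM, Krueppel-like factor 11 (LOC117402481) from 47.3 ± 41.9 to 3.59 ± 0.938, and d2hgdh, which oxidises D-2-hydroxyglutarate, from 31.9 ± 16.6 to 2.81 ± 1.96. Dipeptidase 2-like LOC117424451 fell from 71.1 ± 89.3 to 2.81 ± 1.9 FPKM, erythroid membrane-associated protein-like LOC131709684 from 22.7 ± 26.4 to 0.771 ± 0.453, cortactin-binding protein 2-like LOC117419751 from 43.0 ± 36 to 3.21 ± 0.903, saxo4 from 121.8 ± 92.1 to 10.9 ± 2.62, mpnd from 208.7 ± 141 to 19.5 ± 2.93 and si:ch211-250c4.5, annotated as coiled-coil domain-containing protein 110, from 26.3 ± 17.9 to 1.66 ± 0.717. LOC117395457 averaged 46.29, LOC117968291 16.34, LOC117424451 19.74, LOC117419751 22.37 and LOC117402481 23.1 FPKM without commercial feed library 2. neil1 averaged 5.499, LOC117424451 1.718 and d2hgdh 1.799 FPKM without Limnodrilus library 3. LOC131709684 averaged 7.507 FPKM without commercial feed library 3. saxo4 averaged 72.63 FPKM without commercial feed library 1.

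**Figure D2:**
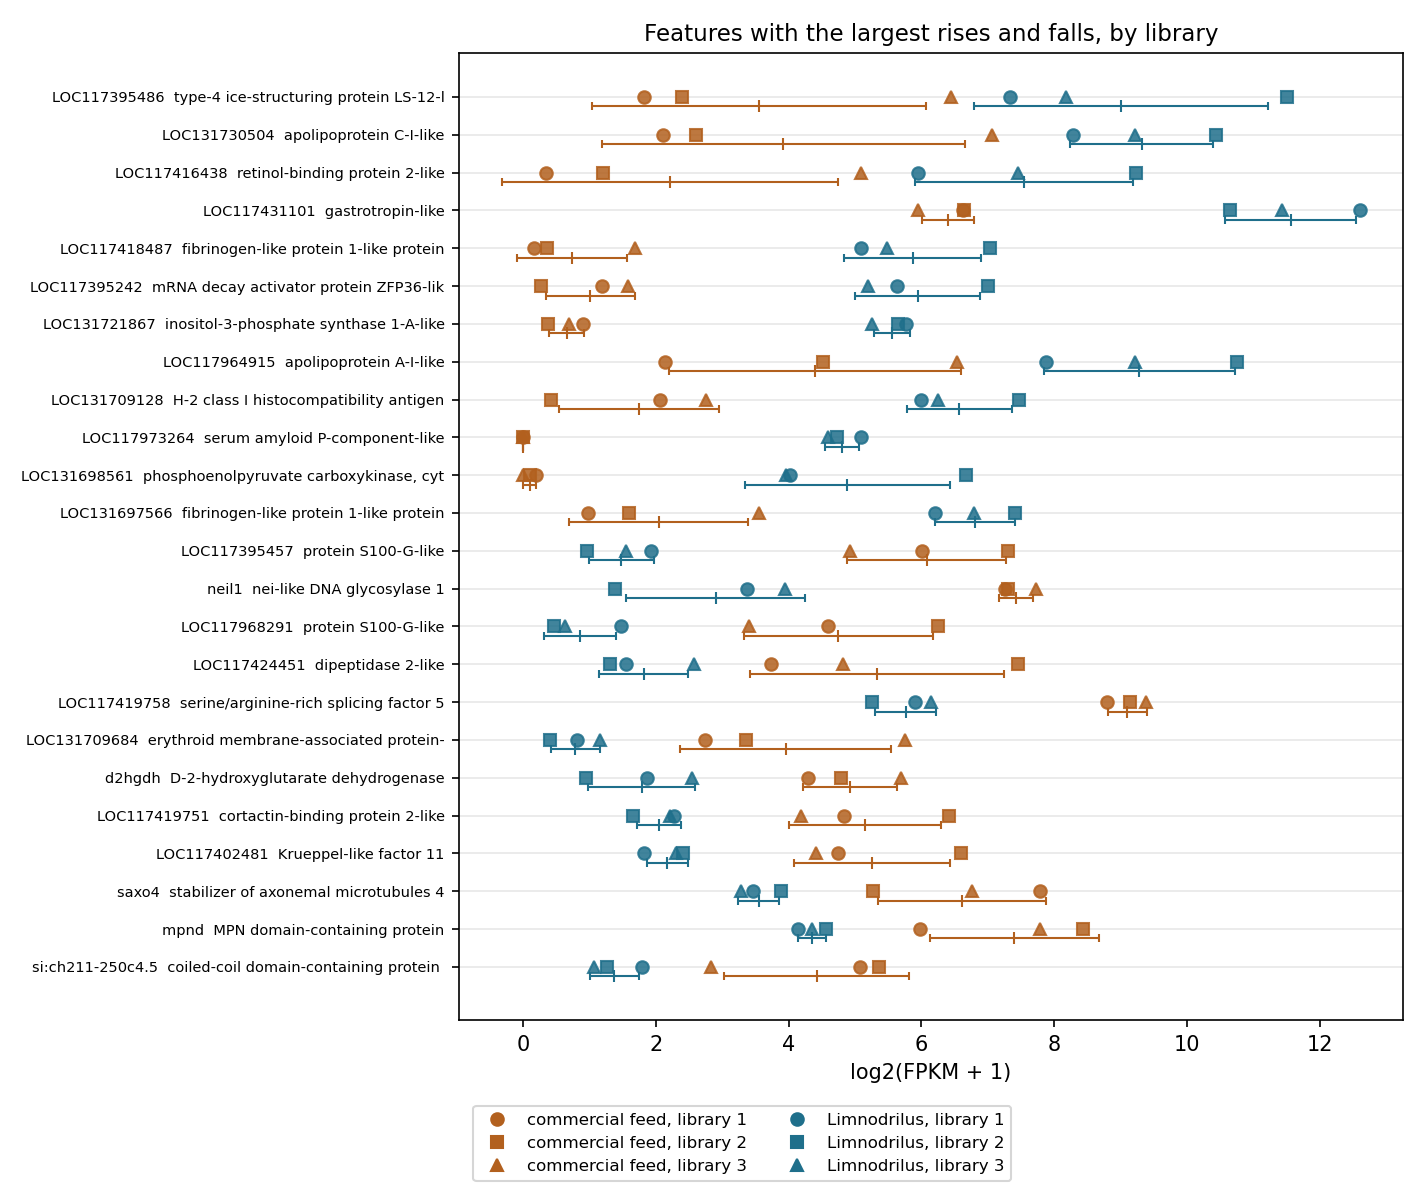
Values of the 12 features with the largest rises and the 12 with the largest falls with Limnodrilus, on the log2(FPKM + 1) scale. Each symbol is a library, and the bar under the symbols gives the mean and SD of the 3 libraries of a diet. The gastrotropin-like locus averaged 85.7 FPKM with commercial feed and 3515 with Limnodrilus.

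Of the 28 gene lists tested, camera called 10, of which 9 were higher and 1 lower with Limnodrilus. With an estimated correlation between genes in place of the preset one, camera called 0 lists, and 2 had an unadjusted p under 0.05. Fry called 6 by its directional test. Without commercial feed library 1 camera called 6 lists.

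Chaperones and genes of the unfolded protein response rose as a group. Of 60 features, 31 rose, 0 fell and 29 did not pass the test, with a median log2 fold change of 1.47 (camera adjusted p = 4.28e-08, and adjusted p = 0.220 with an estimated correlation). Adjusted over the list alone, 38 rose and 1 fell. The list averaged 3.30, 3.29 and 3.33 in the commercial feed libraries and 4.88, 4.71 and 4.80 with Limnodrilus. Calreticulin (LOC117401218) and calnexin-like LOC117431551, lectin chaperones of the endoplasmic reticulum, went from 3.09 ± 1.65 to 48.5 ± 12 and from 7.26 ± 2.29 to 70.6 ± 7.09 FPKM. MANF-annotated LOC117963480 went from 2.43 ± 0.912 to 38.2 ± 9.88 and heat shock 70 kDa protein 4-like LOC117413381 from 9.58 ± 2.26 to 62.8 ± 5.78. The most abundant member, hsp90ab1, averaged 250.9 ± 119 and 611.7 ± 169 FPKM and did not pass (adjusted p = 0.0727).

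Of 30 features of cholesterol biosynthesis, 19 rose, 1 fell and 10 did not pass, with a median log2 fold change of 1.93 (camera adjusted p = 4.70e-08, and adjusted p = 0.681 with an estimated correlation). Adjusted over the list alone, 25 rose and 1 fell. Squalene monooxygenase (sqlea) went from 0.513 ± 0.475 to 29.9 ± 7.16 FPKM, methylsterol monooxygenase (msmo1) from 0.799 ± 0.183 to 31.5 ± 19.6, lanosterol 14-alpha demethylase LOC117399525 from 0.534 ± 0.509 to 19.01 ± 7.07 and delta(24)-sterol reductase LOC117416469 from 0.381 ± 0.25 to 10.8 ± 3.26. The insulin-induced gene 1 locus LOC131736982 averaged 7.67 ± 5.02 and 56.5 ± 56.2 FPKM and did not pass (adjusted p = 0.0536). msmo1 averaged 20.45 FPKM without Limnodrilus library 2. LOC131736982, which did not pass, averaged 24.09 FPKM without Limnodrilus library 2 and 4.916 without commercial feed library 3.

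Of 41 features of lipid absorption and lipoprotein assembly, 15 rose and 26 did not pass, with a median log2 fold change of 2.19 (camera adjusted p = 1.05e-05, and adjusted p = 0.846 with an estimated correlation). Adjusted over the list alone, 29 rose. The list averaged 1.73, 2.39 and 4.11 in the commercial feed libraries and 4.50, 5.92 and 4.87 with Limnodrilus. Besides the gastrotropin-like loci, perilipin-2-like LOC117420754, a coat protein of lipid droplets, went from 4.72 ± 0.61 to 78.2 ± 43.7 FPKM and SAR1b LOC117413507, which takes part in chylomicron transport, from 19.8 ± 6.61 to 112.8 ± 8.13. The second gastrotropin-like locus, LOC117964583, went from 18.9 ± 7.83 to 375.1 ± 261. Intestinal fatty acid-binding protein LOC117409347 went from 291.5 ± 398 to 3896 ± 3173 FPKM, and was at 31.5, 93.5 and 749 in the 3 commercial feed libraries. In the brush-border list 8 of 35 features rose, 27 did not pass and the median was 1.86, or 2.08 with 1 feature at 0 in commercial feed set to its bound (camera adjusted p = 0.00367, and adjusted p = 0.923 with an estimated correlation), with 12 rising when adjusted over the list alone. The ileal bile acid transporters LOC117405829 and slc10a2 went from 1.17 ± 0.971 to 41.7 ± 20.4 and from 0.676 ± 0.779 to 15.5 ± 15.8 FPKM, and the neutral amino acid transporter LOC117400070 from 20.4 ± 23 to 219.2 ± 28.4. The proton-coupled amino acid transporter LOC117413057 went from 1.10 ± 0.408 to 5.18 ± 1.49, while the peptide transporter LOC117406526 ranged from 0.573 to 756 FPKM within the commercial feed libraries and did not pass (adjusted p = 0.348). The brush-border call was lost without commercial feed library 1 (adjusted p = 0.0925), without libraries 1 and 2 (0.56), with 1 feature per symbol (0.0731) and with fry (0.227), and the lipid absorption call with fry (0.105). LOC117405829 averaged 0.7576, LOC117400070 7.481 and LOC117409347 62.53 FPKM without commercial feed library 3. slc10a2 averaged 6.392 and LOC117964583 226.2 FPKM without Limnodrilus library 1. LOC117409347 averaged 2128 FPKM without Limnodrilus library 2.

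Tight junction and barrier genes rose in 13 of 33 features, with 20 not passing and a median of 1.47 (camera adjusted p = 1.10e-05, and adjusted p = 0.656 with an estimated correlation). There were 17 rises when adjusted over the list alone. Junctional adhesion molecule A-like LOC117397087 went from 15.1 ± 9.41 to 153.8 ± 36.8 FPKM, claudin-15-like LOC117967914 from 1.63 ± 1.33 to 10.2 ± 2.79 and the MARVEL domain-containing 2-like loci LOC117973491 and LOC117403807 from 1.60 ± 0.757 to 19.2 ± 2.97 and from 0.629 ± 0.323 to 4.94 ± 0.299. Cadherin-1-like LOC117424675 averaged 79.9 ± 34.7 and 150.7 ± 19.9 FPKM and did not pass (adjusted p = 0.150). LOC117397087 averaged 9.684 and LOC117967914 0.8949 FPKM without commercial feed library 3.

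Xenobiotic and antioxidant genes rose in 20 of 47 features, with 27 not passing and a median of 1.21 (camera adjusted p = 0.00127, and adjusted p = 0.810 with an estimated correlation). Adjusted over the list alone, 23 rose. Glutathione peroxidase 1-like LOC117411984 went from 176.3 ± 64 to 932.7 ± 70.7 FPKM, glutathione S-transferase P-like LOC117408499 from 6.77 ± 2.8 to 148.4 ± 114, thioredoxin-like LOC117421010 from 53.8 ± 10.7 to 403.4 ± 159 and the transcription factor NRF2-like LOC117401850 from 5.94 ± 0.902 to 25.98 ± 2.91. In the list of chitin digestion and lysosomal hydrolases 11 of 39 features rose and 28 did not pass, with a median of 1.13 (camera adjusted p = 0.00367, and adjusted p = 0.923 with an estimated correlation), and 11 rose when adjusted over the list alone. The 11 members that rose encode lysosomal proteins and 0 of them are chitinases: acid lipase LOC117414642 went from 1.05 ± 0.0569 to 13.2 ± 1.57 FPKM and LOC117418515 from 10.3 ± 3.25 to 50.02 ± 5.96, legumain-like LOC117963871 from 10.6 ± 3.58 to 210.8 ± 181 and prosaposin-like LOC117969813 from 7.28 ± 2.18 to 29.7 ± 5.3. The chitinase-like locus LOC117965952 did not pass (adjusted p = 0.213), at 0.607, 5.39 and 1091 FPKM in the commercial feed libraries. This list's call was lost without commercial feed library 1 (adjusted p = 0.0928), with 1 feature per symbol (0.0731) and with fry (0.151). LOC117408499 averaged 84.11 and LOC117963871 107.8 FPKM without Limnodrilus library 1.

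Fatty acid synthesis and desaturation genes rose in 7 of 20 features, with 13 not passing and a median of 1.08 (camera adjusted p = 0.00367, and adjusted p = 0.769 with an estimated correlation), and 7 rose when adjusted over the list alone. This list's call was lost with a mean of at least 5 FPKM (adjusted p = 0.0812) and without commercial feed libraries 1 and 2 (0.124). Fatty acid synthase-like LOC117424309 went from 0.090448 ± 0.0928 to 4.2038 ± 1.29 FPKM, and the elongases LOC117403386, LOC117435692 and LOC117417739 from 2.34 ± 1.78 to 52.8 ± 40.2, from 0.432 ± 0.474 to 24.8 ± 24.9 and from 0.515 ± 0.262 to 4.96 ± 0.78. Desaturase-like LOC117415462 averaged 18.9 ± 12.7 and 88.5 ± 111 FPKM and did not pass (adjusted p = 0.259). Of 19 enteroendocrine and neural marker features only ret rose, from 0.447 ± 0.363 to 2.62 ± 0.569 FPKM, and the median was 1.29 (camera adjusted p = 0.0395, and adjusted p = 0.681 with an estimated correlation); adjusted over the list alone, 0 passed. LOC117420535, a ubiquitin hydrolase L1-like locus, averaged 25.5 ± 35.5 and 85.4 ± 57.4 and did not pass. This call was lost without commercial feed library 1 (adjusted p = 0.0643), without library 2 (0.0987), without both (0.131), with a mean of at least 5 FPKM (0.0812), with limma-voom (0.0667), with 1 feature per symbol (0.0574) and with the length trend removed and the level kept (0.0661). The fibroblast and matrix list was the list called lower, with a median of -0.21 over 46 features of which 1 rose and 1 fell (camera adjusted p = 0.0395, and adjusted p = 0.923 with an estimated correlation), and 1 fell when adjusted over the list alone. Collagen alpha-1(I)-like LOC117394484 went from 4.03 ± 2.26 to 0.258 ± 0.0413 FPKM and LOC117968958 from 1.36 ± 0.592 to 4.12 ± 0.691, while the most abundant locus, LOC117434956, averaged 447.2 ± 337 and 175.1 ± 55.1 and did not pass (adjusted p = 0.482). This call was lost under median-of-ratios scaling (adjusted p = 0.0788), quantile normalization (0.136), limma-voom (0.0606), 1 feature per symbol (0.0731), fry (0.897) and the removal of the trend with gene length (0.241, or 0.142 with the level kept). It was also lost without commercial feed library 1 (adjusted p = 0.597), without library 2 (median 0.059, adjusted p = 0.352) and without Limnodrilus library 2 (adjusted p = 0.184), and without commercial feed libraries 1 and 2 the median was 0.822. LOC117403386 averaged 1.333 FPKM without commercial feed library 2. LOC117403386 averaged 30.09 and LOC117435692 10.43 FPKM without Limnodrilus library 2. Of features that did not pass, LOC117415462 averaged 24.25 FPKM without Limnodrilus library 2 and 11.58 without commercial feed library 3, and LOC117420535 52.26 without Limnodrilus library 1 and 5.035 without commercial feed library 1.

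**Figure D3:**
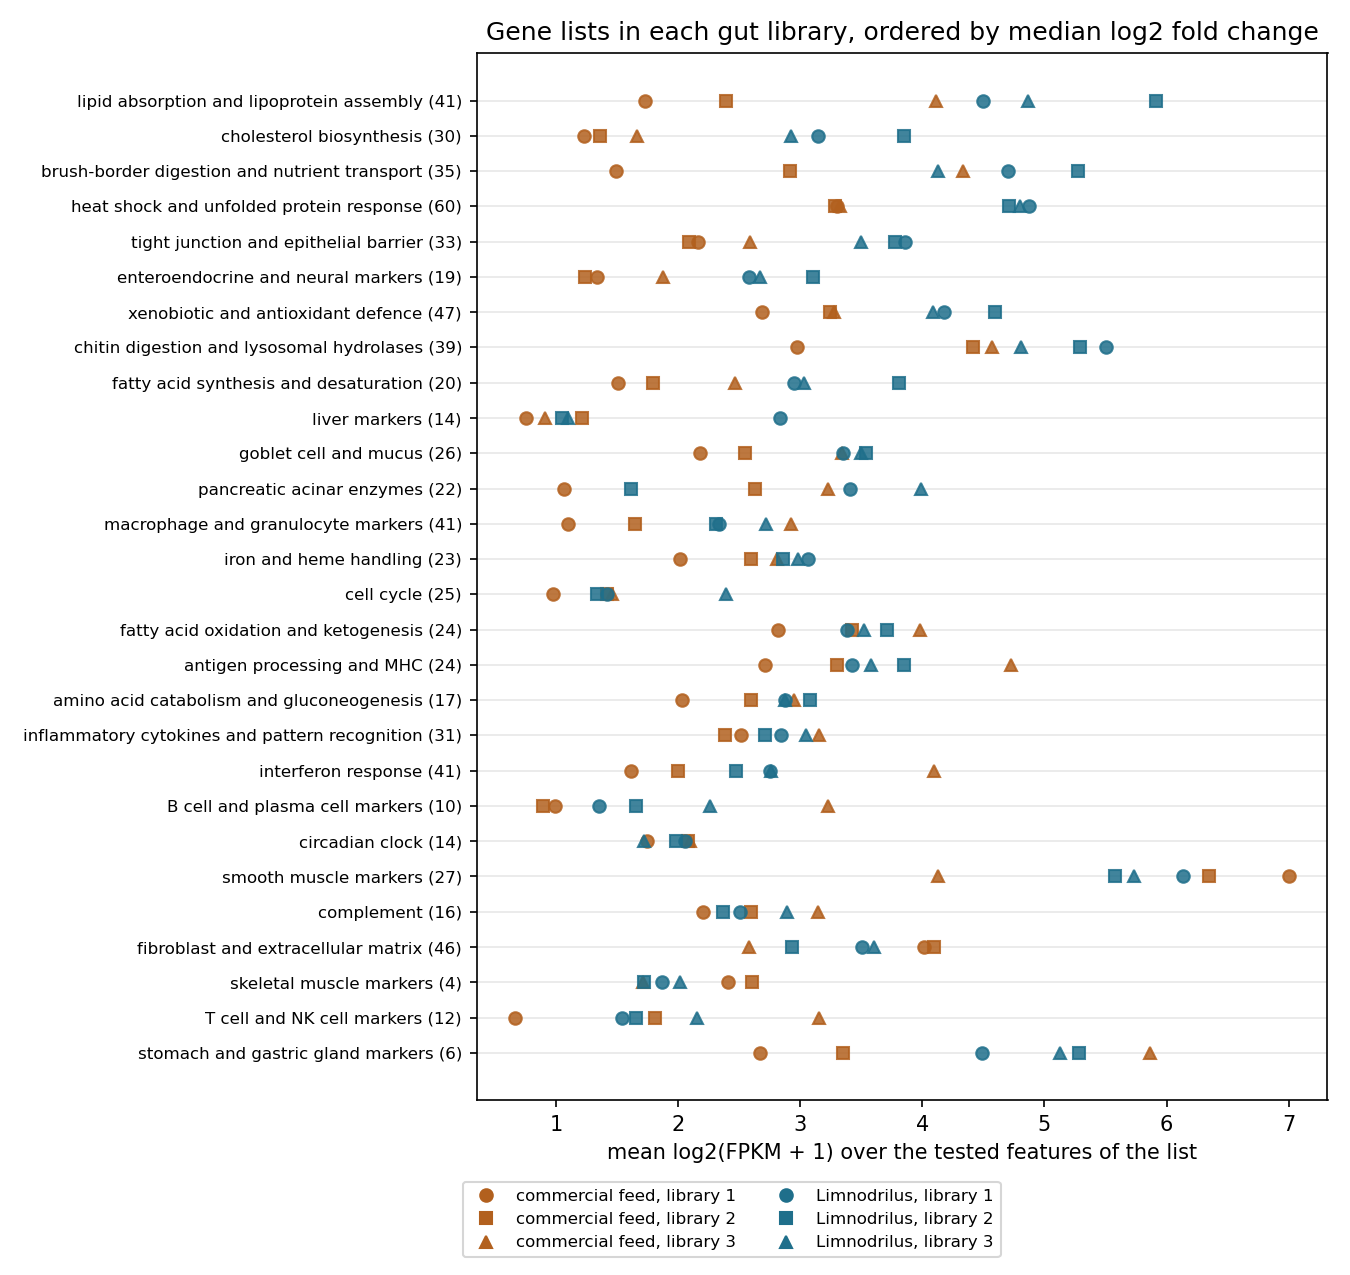
Mean log2(FPKM + 1) of each gene list in each of the 6 libraries, with the number of tested features in brackets, ordered by the median log2 fold change. Each symbol is a library, coloured by diet. The heat shock list lies at 3.29 to 3.33 in the commercial feed libraries and at 4.71 to 4.88 with Limnodrilus, and smooth muscle markers spread from 4.13 to 7.00 within commercial feed.

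The other lists were not called by camera, and their counts stand beside 3321 rises and 861 falls among all 23644 tested features. Camera's direction was down while the median was above 0 for the fatty acid oxidation (median 0.3, mean 0.129), inflammatory (0.137, 0.180), antigen processing (0.221, 0.037) and interferon (0.077, 0.094) lists, since it compares a list with all other features. For B cell (mean 0.054) and stomach markers (median -0.402, mean 1.003) median and mean differ in sign. Of markers of immune cells, B cell (10 features, median -0.01) and T and NK cell (12 features, -0.34) features all failed to pass; the B-cell linker LOC117418546 averaged 14.4 ± 17.7 and 4.23 ± 1.19 FPKM and il7r 9.85 ± 8.99 and 19.9 ± 4.77. Of 41 macrophage and granulocyte features 2 rose, macrosialin-like LOC117967610 from 1.24 ± 1.1 to 23.2 ± 3.44 FPKM and cytochrome b-245 light chain LOC117424066 from 9.23 ± 9.57 to 38.3 ± 4.93. The interferon list had 2 rises among 41 features, irf9 from 2.22 ± 1.81 to 8.86 ± 1.22 and LOC117418098 from 0.393 ± 0.412 to 2.48 ± 0.431. The antigen processing list had 1 rise among 24, beta-2-microglobulin-like LOC131696861 from 110.4 ± 92.5 to 397.4 ± 29.2. The neighbouring beta-2-microglobulin locus LOC117398321, the list's most abundant member, averaged 308.4 ± 236 and 409.9 ± 124 FPKM. LOC117398321 did not pass (limma adjusted p = 0.469), and averaged 173.3 FPKM without commercial feed library 3. The inflammatory list had 1 among 31, interleukin-8-like LOC117421434 from 0.372 ± 0.645 to 3.27 ± 2.08, and NF-kappa-B inhibitor alpha-like LOC117421916 averaged 250.1 ± 152 and 220.3 ± 49.2. Complement had 1 rise among 16, C3-like LOC131706606 from 0.321 ± 0.27 to 3.90 ± 2.81. Adjusted over the list alone, 1 macrophage feature and 0 features of the other immune lists passed. Goblet cell and mucus genes had 5 rises among 26 features, and 5 when adjusted over the list alone, among them mucin-2-like LOC131737439, from 10.5 ± 5.04 to 36.1 ± 11.7 FPKM, and zymogen granule protein 16-like LOC131707229, from 39.4 ± 18.4 to 193.1 ± 128. LOC117421434 averaged 2.079 FPKM without Limnodrilus library 1. LOC131696861 averaged 58.27, irf9 1.18, LOC117967610 0.6111 and LOC117424066 3.736 FPKM without commercial feed library 3. LOC131706606 averaged 2.298 FPKM without Limnodrilus library 3. LOC131707229 averaged 120 FPKM without Limnodrilus library 2. Without commercial feed library 3, LOC117421916, LOC117418546 and il7r, which did not pass, averaged 164.9, 4.406 and 5.342 FPKM.

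Smooth muscle markers had 2 rises among 27 features, the myosin light chain 9 loci LOC117399231 (40.4 ± 4.32 to 154.2 ± 15 FPKM) and LOC117394724 (125.8 ± 16.3 to 329.1 ± 12.1), while the locus LOC131702058, was at 3580.9, 1718.5 and 173.84 in the commercial feed libraries and did not pass. Iron and heme genes had 4 rises among 23, including the iron regulatory protein 2-like loci LOC117428368 (6.41 ± 0.982 to 35.5 ± 3.7) and LOC117429403 (7.81 ± 3.1 to 23.9 ± 3.17); slc40a1, the iron exporter, averaged 55.5 ± 34.1 and 31.8 ± 9.98 and did not pass. Circadian clock genes went both ways, with 2 rises and 3 falls among 14 features. CLOCK-like LOC117409483 went from 0.184 ± 0.0995 to 2.66 ± 0.606 FPKM and NFIL3-annotated LOC117409603 from 0.130 ± 0.0291 to 1.96 ± 1.19, whereas the period 1-like loci LOC117967971 and LOC117969081 went from 7.00 ± 4.03 to 0.827 ± 0.23 and from 2.59 ± 0.662 to 0.430 ± 0.0973. The pancreatic list had 1 fall among 22, the granule membrane glycoprotein LOC117402991 from 8.14 ± 1.3 to 0.464 ± 0.0926 FPKM, and the lipase LOC117417614 ranged from 52.7 to 2957.4 within commercial feed. Fatty acid oxidation had 1 rise among 24 features, angiopoietin-related protein 4-like LOC117966247 from 0.358 ± 0.226 to 8.18 ± 1.19. The amino acid catabolism and gluconeogenesis list had 2 among 17. These were mitochondrial aspartate aminotransferase-like LOC117425021 from 22.1 ± 1.26 to 90.6 ± 17.7, and LOC117415321 from 0.0735 ± 0.127 to 3.59 ± 0.651. LOC117415321, annotated as 4-hydroxyphenylpyruvate dioxygenase-like protein, matched the listed hpd with the name's ending dropped, so it may be another gene. The carboxykinase locus LOC131698561, which rose, was not matched to this list although the list holds pck1. For these lists, adjusted over the list alone, 5 iron and heme features rose and 2 fell, 2 circadian features rose and 3 fell, 2 smooth muscle, 2 amino acid catabolism and 1 fatty acid oxidation features rose and 1 pancreatic feature fell. Fry's mixed test, which takes change in either direction, gave adjusted p = 0.000622 for the circadian, fatty acid oxidation and amino acid catabolism lists. It gave 3.07e-05 for iron and heme, 0.0749 for pancreatic and 0.601 for smooth muscle features. Fry does not compare a list with the other features, so broad change can also call a list. Cell cycle (25 features), liver (14), stomach (6) and skeletal muscle (4) lists held 0 called features. Liver markers averaged 2.835, 1.046 and 1.096 on the log2(FPKM + 1) scale in Limnodrilus libraries 1, 2 and 3, and 0.753, 1.213 and 0.907 with commercial feed. Cell cycle genes averaged 1.413, 1.334 and 2.388 in the Limnodrilus libraries and 0.976, 1.414 and 1.458 with commercial feed. Each list was thus high in a single Limnodrilus library, and the cause was not tested.

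The most abundant features of both diets were mitochondrial. COII averaged 69066 ± 98530 FPKM with commercial feed, with 182830 in library 1, and 37418 ± 13470 with Limnodrilus, and did not pass (adjusted p = 0.889); COIII and COI did not pass either (adjusted p = 0.793 and 0.780). Mitochondrial 16S rRNA (Q747_mgr01) went from 6870 ± 2684 to 955.2 ± 344 FPKM (adjusted p = 0.0136). The ribosomal protein eL32 (LOC117413906) averaged 5036 ± 2174 and 2918 ± 221 and did not pass. COII averaged 12190 FPKM without commercial feed library 1.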

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

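Chosen after seeing the data were limma-voom, thinned reads, leaving out rRNA, tRNA and mitochondrial features, the 2 removals of the trend with gene length, and leaving out commercial feed libraries 1 and 2. The 4182 calls were 2625 with a mean FPKM of at least 5 (fewer features tested), 2607 with the replicate block and 6764 at an unadjusted p under 0.05 and a fold of at least 2. The 3321 higher were 1992 with a mean of at least 5, 2107 with the block, 2054 with the length trend removed and 1981 without commercial feed libraries 1 and 2. The 861 lower were 556 with no filter, 1492 under median-of-ratios scaling, 1643 under quantile normalization, 500 with the block, 1601 with the length trend removed, 1920 without commercial feed libraries 1 and 2 and 1788 at the unadjusted threshold. Of these, the scalings and the removal of the length trend re-centre each library; the cause of the others was not tested. Leaving out 1 library gave 638 to 6295 calls, 563 to 4883 higher, 66 to 1412 lower and 6 to 12 lists. The 10 called lists were 0 with camera at an estimated correlation (4 lists had an unadjusted p under 0.1 and 2 under 0.05), 6 with fry and 6 with 1 feature per symbol. The lists for chaperones, cholesterol, junctions, lipid absorption and xenobiotics were called in each of the 21 settings with camera's preset correlation. The replicate number was not used as a pair: residuals of libraries with the same number correlated at 0.187, -0.069 and 0.075, and 3 of 6 libraries correlated best with their own number. The planned count-based test was not run because the table holds FPKM. Of 85 called named genes, 35 kept their call in the settings run and 0 turned direction.

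Results that changed sign follow as log2 fold changes, or medians for lists; of them only the fibroblast and extracellular matrix list had been called, and the cause was not tested. With log2(FPKM + 0.1) these were LOC117411234 0.034 and T cell and NK cell markers 0.17. With no filter on low values they were complement 0.052, B cell and plasma cell markers 0.083 and circadian clock 0.074. With a mean FPKM of at least 5 they were T cell and NK cell markers 0.174 and circadian clock 0.236. With TPM, LOC117421916 0.089, LOC117411234 0.125, B cell and plasma cell markers 0.054 and circadian clock 0.035. Under median-of-ratios scaling, LOC117417614 -0.292, hadh -0.131, LOC131720984 -0.12, COII -0.065, inflammatory cytokines and pattern recognition -0.028 and interferon response -0.12. Under quantile normalization, hadh -0.143, LOC131702058 0.182, LOC131720984 -0.063, COII 0, amino acid catabolism and gluconeogenesis -0.129, inflammatory cytokines and pattern recognition -0.144, antigen processing and MHC -0.093 and interferon response -0.151. With limma-voom on recovered reads, LOC117411234 0.033 and T cell and NK cell markers 0.414. With reads thinned to equal totals, LOC117411234 0.027. With rRNA, tRNA and mitochondrial features left out, LOC117417614 -0.068. With the trend with gene length removed, LOC117417614 -0.342, hadh -0.198, LOC131720984 -0.197, LOC131700563 -0.04, fatty acid oxidation and ketogenesis -0.067, amino acid catabolism and gluconeogenesis -0.144, inflammatory cytokines and pattern recognition -0.182, antigen processing and MHC -0.113 and interferon response -0.286. With that trend removed and the level kept, LOC117417614 -0.057 and interferon response -0.002. Without commercial feed libraries 1 and 2, LOC117417614 -2.238, LOC117406526 -2.557, LOC117398321 -0.541, LOC117435108 -0.359, LOC117400300 -0.918, LOC117965952 -1.409, LOC131702058 2.41, LOC117411234 2.48, LOC117434956 1.113, LOC117431837 -0.409, LOC131700563 -0.428, pancreatic acinar enzymes -0.317, fatty acid oxidation and ketogenesis -0.328, amino acid catabolism and gluconeogenesis -0.314, inflammatory cytokines and pattern recognition -0.241, antigen processing and MHC -1.182, interferon response -1.592, macrophage and granulocyte markers -0.319, smooth muscle markers 1.936 and fibroblast and extracellular matrix 0.822.

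Leaving out 1 library gave these ranges for results that changed sign: LOC117417614 -1.744 to 1.148, hadh -0.135 to 0.391, LOC117421916 -0.423 to 0.428, LOC117418546 -1.807 to 0.399, f2 -1.141 to 0.04, LOC131702058 -1.417 to 0.761, LOC117411234 -1.276 to 0.962, LOC117431837 -0.953 to 1.708, LOC131720984 -0.187 to 0.702, LOC131700563 -0.218 to 0.694, COII -0.501 to 1.555, COIII -0.287 to 1.375, COI -0.534 to 1.762, fatty acid oxidation and ketogenesis -0.014 to 0.513, antigen processing and MHC -0.304 to 0.626, interferon response -0.44 to 0.929, complement -0.384 to 0.093, B cell and plasma cell markers -0.392 to 0.617, T cell and NK cell markers -0.779 to 0.246, smooth muscle markers -1.045 to 0.596, fibroblast and extracellular matrix -0.811 to 0.059 and circadian clock -0.212 to 0.068. Without commercial feed libraries 1 and 2 the remaining library is assumed to vary like the other diet, and camera then called antigen processing (adjusted p = 0.000662), interferon response (3.26e-06), B cell (0.00198) and T cell markers (0.00163) lower, and smooth muscle (1.05e-07) and fibroblast (0.00137) higher. Without commercial feed library 3 the calls went the other way for smooth muscle (median -1.045, adjusted p = 2.55e-06) and fibroblast (-0.811, 1.47e-07), and macrophage markers were called higher (1.116, 0.009). Without Limnodrilus library 2 pancreatic markers were called higher (1.196, 0.0359).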

Other observations

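The 16 lists in these paragraphs were added after the fold changes had been seen, so their counts describe these libraries and are not independent tests. With Limnodrilus the chaperonin, proteasome, tRNA ligase and vesicle coat lists each held at least 15 rises and 0 falls, and cytosolic ribosomal proteins held 2 rises and 6 falls. Of 22 features of the T-complex protein 1 chaperonin 18 rose, with a median log2 fold change of 1.84 (camera adjusted p = 1.79e-07, and adjusted p = 0.364 with an estimated correlation), among them LOC131697385, subunit beta, from 9.52 to 69.9 FPKM. Of 74 proteasome features 40 rose (median 1.301, camera adjusted p = 1.10e-09, and adjusted p = 0.364 with an estimated correlation), such as LOC117434580, subunit beta type-3, from 7.89 to 56.3. Of 38 cytosolic aminoacyl-tRNA ligase features 19 rose (median 1.26, camera adjusted p = 7.25e-06, and adjusted p = 0.378 with an estimated correlation), and of 29 coatomer and COPII features 15 rose (median 1.34, camera adjusted p = 1.42e-06, and adjusted p = 0.378 with an estimated correlation), with Sec23A LOC117410375 at 1.25 and 19.4 FPKM. Nuclear-encoded oxidative phosphorylation had 38 rises and 2 falls among 124 features (median 0.78), mitochondrial ribosomal proteins 22 rises among 120 (median 0.66) and V-type proton ATPase subunits 6 rises among 34 (median 0.71). With an estimated correlation the camera adjusted p of each was 0.617. Over all features tested, 3321 of 23644 rose, with a median of 0.243, so the counts of the last 2 lists lie near the general share. The 153 cytosolic ribosomal protein features had 2 rises and 6 falls (median -0.34, camera adjusted p = 6.59e-06, and adjusted p = 0.617 with an estimated correlation).

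SR splicing factors and CLK kinases, which phosphorylate them, fell with Limnodrilus in 16 of 36 features, with 2 rises (median -1.09, camera adjusted p = 7.59e-12, and adjusted p = 0.364 with an estimated correlation). clk4b went from 760 to 103 FPKM, srsf5b from 662 to 90.7 and CLK1-like LOC131699419 from 642 to 122. Ribosomal RNA features fell in 20 of 36 (median -1.57, or -1.496 with 6 features at 0 with Limnodrilus set to their bound, camera adjusted p = 9.98e-16, and adjusted p = 0.364 with an estimated correlation), which depends on what oligo(dT) capture lets through. Small nuclear and nucleolar RNAs had 41 rises and 3 falls among 216, but 23 of these calls are of features at 0 in each library of one diet, some with a bound under 1-fold. The median log2 fold change of this list was 0.946, or 0.681 with features at 0 set to their bound (camera adjusted p = 0.00108, and adjusted p = 0.364 with an estimated correlation). Its library means did not overlap (1.28, 1.437 and 1.762 against 2.595, 2.214 and 2.383). The share of reads of these RNAs did overlap between diets (0.0129%, 0.0196% and 0.0245% against 0.0213%, 0.0154% and 0.0192%), so no direction is read from them. The 22 core histone features had a median of 0.04, with 2 rises.

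Chosen after the result was seen were the thinning, leave-out and gene-length tests, and the comparison of chaperone and cholesterol lists with keratins and junction genes; the predictions for keratins and immediate early genes were stored after their values had been displayed. Of the calls, 79.4% were higher with Limnodrilus. The share was 79.5% with reads thinned to equal totals, which argues against counting noise from unequal depth as the whole cause. FPKM is already scaled to the library total and the same features were tested, so thinning tests little else about depth. Without rRNA, tRNA and mitochondrial features the share was 75.4%, which argues against those features as the whole cause. Median-of-ratios scaling gave 59.97%, so the imbalance may follow the scaling of the libraries. Removing the trend with gene length gave 78.82% with each library's level kept and 56.2% without it, so the share follows that level. That test cannot decide on shorter RNA in the commercial feed libraries, which would make log2 fold changes rise with gene length. With features classed by length, the median from the shortest to the longest class was 0.027, 0.167, 0.355, 0.294, 0.184 and -0.054. The fall over the longer classes argues against shorter RNA as the whole cause for those features. The rise over the shorter classes goes with it, so shorter RNA stays open for the shorter features. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: the real split, 1 of 10, called 4182 features with limma and the highest other called 0.

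Of lipid absorption, brush-border and junction features 15 of 41, 8 of 35 and 13 of 33 rose with Limnodrilus, and the adjusted p of the lists was 0.846, 0.923 and 0.656 with an estimated correlation. Removing the length trend left the lowest of the 3 medians at 1.167, so a trend with gene length does not account for these rises. Over all tested features log2 fold change and length correlated weakly (Spearman -0.042), so there was little trend to remove. RNA loss unrelated to gene length was not tested. Keratins 8, 18 and 19, in none of the 3 lists, had a median of 1.329 with 5 of 18 features rising, so a smaller share of epithelium in the commercial feed samples may account for part of the rise. Smooth muscle markers were high in commercial feed libraries 1 and 2 and low in library 3, with a median of -0.14 between diets, so one tissue share does not describe the 3 libraries. Diet, cage and any difference in sampling cannot be separated in this design.

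Of 60 chaperone features 31 rose and of 30 cholesterol synthesis features 19 rose and 1 fell with Limnodrilus, and the adjusted p of the lists was 0.220 and 0.681 with an estimated correlation. The chaperone median lay 0.058 above that of keratins and junction genes (bootstrap interval over list members -0.288 to 0.631) and the cholesterol median 0.51 above (0.074 to 1.045). These intervals treat features as independent and leave out the spread between libraries. A smaller share of epithelium thus cannot be told apart for chaperones, and the cholesterol difference does not exclude it either. Immediate early genes had a median of 0.66 (33 features, 6 rising), or 1.04 with Krueppel-like factors 2, 4 and 6 added by a looser match of names (39 features, 9 rising), and their library means overlapped (2.994, 2.701 and 3.435 against 3.477, 4.896 and 3.142). That median was 0.247 without Limnodrilus library 2, 0.41 without commercial feed library 2, 1.102 without Limnodrilus library 1 and 1.4 without Limnodrilus library 3, so handling before sampling also cannot be told apart. Cold-inducible RNA-binding proteins had a median of 1.433 over 4 features, of which 2 rose, so the fall that warmer water or tissue in the Limnodrilus group would give was not seen. These few features are neighbouring loci on NC_081237.1 and NC_081235.1 that may share reads, so they do not settle the question of temperature. A response to the diet itself stays open and untested.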
